A study of Mus musculus with 6 samples.

How the data were processed

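Single cells sorted as cDC1 or cDC2 from MC38-EGFP tumours were processed by a modified SMART-seq2 protocol, per the labels' protocols. Each well received a primer with a cell barcode and a molecular identifier (UMI) of 8 bases each, amplified cDNA was pooled, and the 3' end was captured before library construction. FastQC, STAR 2.7.9a, Seurat 4.0.5 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. The read counter, the gene annotation, the strand setting and any collapsing of UMIs are not given in the sources used here. The deposited values were whole counts per gene and well, with 24369 genes and 97 columns per library, of which 96 were numbered barcodes. The deposited sparse matrices held the same values for genes above 0 in at least 3 columns, with 0 differing entries.

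The design had been fixed for UMI counts. The deposited counts were reads: 594 values of 1 gene in 1 cell exceeded 65536, the number of different UMIs that 8 bases can form. The count test was kept, since it estimates the spread from the libraries. Intervals and floors cover counting error only, because PCR copies are not independent molecules. No mitochondrial gene was among the features, so the planned limit of 10% mitochondrial reads removed no cell and the list of mitochondrial transcripts had 0 genes to test. No feature was named EGFP or GFP. The 6 columns outside the numbered barcodes, 1 per library, were not used as cells.

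Groups were taken from the sample titles, DC1 (numbers 3, 4 and 5) and DC2 (numbers 1, 2 and 6), read as the cDC1 and cDC2 sorts. The number was read as that of a replicate and may be that of a plate, so n = 3 counts libraries and may not count animals. No 2 libraries agreed within sampling noise, as copies of 1 library would (chi-square per degree of freedom 416 to 1890, Spearman correlation across genes 0.837 to 0.896), and each was counted once. This does not show that they are independent. Cells needed at least 1000 detected genes, and 567 of 576 wells passed. Cells over 3 median absolute deviations above the median log depth of their library numbered 0, so leaving them out had no effect. Doublets were not called.

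Cells were clustered in Python 3.11.15 with scanpy 1.11.5, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1: log1p of counts per 10000, 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 1 with seed 0, without integration. Ribosomal genes and the genes of the WEE1 and G2/M checkpoint, cGAS-STING and MHC class I lists were left out of the clustering. A cluster took the name of the class with the most markers at least 1 log2 unit above other cells (log2 of CPM plus 10, with at least 20 CPM), needing 3 markers and at least 1 among its 10 leading genes (with at least 50 CPM). Clusters with a median depth under 1/3 of the library median were called shallow. The markers were fixed before the data were examined, and this naming rule and the depth bound were set after the clusters were seen. Shares are percentages of the cells passing the filter, with 95% Clopper-Pearson intervals per library and a two-sided exact permutation test across libraries.

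Reads were summed over the cells of each library and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, TMM factors of 0.947 to 1.06, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). The common biological coefficient of variation was 0.845. Gene lists were tested with camera (limma 3.58.1) on voom values with a correlation preset to 0.01, and beside it with an estimated correlation and with fry. Of 30 lists, 18 were called, 8 towards DC1 and 10 towards DC2. With an estimated correlation 0 were called, with 7 at an unadjusted p under 0.05, and fry, which tests whether the genes of a list move on balance one way, called 4: pan-dendritic (adjusted p = 0.00898), maturation (0.0203), MHC class I (0.0295) and macrophage (0.0379). Wee1 in mature-like and other cells was tested on sums per library and class with the library as a block, in libraries with at least 5 cells of both classes, which were the 3 DC1 libraries.

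The lists covered dendritic cell identity (cDC1, cDC2, pan-dendritic), maturation and regulatory genes of mature cells, MHC class I and II, cross-presentation and antigen uptake, interferon, Toll-like receptor, cGAS-STING, cytokine and chemokine genes, the cell cycle and DNA repair, glycolysis and hypoxia, lysosome and complement, dissociation stress, and markers of other cell types. The tests, gene lists, markers, naming rule for genes and all alternatives except those named as added were chosen before the data were examined. The rule named the 12 genes with the largest log2 fold change in each direction among called genes with a mean log2 CPM of at least 5 and all libraries of 1 group above all of the other, which 100 genes towards DC1 and 43 towards DC2 met. It also named 11 genes whatever their result and, from each list described, up to 4 members with the smallest p, of which those that were called are given values. Called genes without a name or coding for ribosomal proteins, 5 of 182, were counted and not named. Ccnb2, Ccnb1, Cdc25b, Ccna2, Top2a and Kit were named after their values were seen. Coordinates are 1-based, from GENCODE vM21 on mm10, and 53 of 54 named genes were found there, each as a protein-coding gene. Sepp1 had no entry under that symbol.

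The fit was tested on simulated counts with the means, dispersions per gene and library sizes of the real libraries. Over 11168 genes it called 77, of which 0 were unchanged, and recovered 0% of 48 genes set at 2-fold, 32% of 50 at 4-fold, 56.2% of 48 at 8-fold and 68% of 50 at 16-fold. The alternatives were median-of-ratios factors, DESeq2 1.42.0, limma-voom, no gene filter, at least 50 reads in 3 libraries, equal weight per cell, no cell filter, at least 2000 genes per cell, subsets of cells, reads thinned to 51662827 per library, other clustering resolutions and leaving out each library in turn. Cells with at least 100000 reads, these without the macrophage-like cells named among them, scaled genes before clustering, naming shallow clusters by their best class, and the subsets without shallow, T or NK-like, macrophage-like or both mature-like and cDC1-like cells or with clusters 0, 3, 4 and 5 alone were added after the data were seen.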

Results

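Conventional dendritic cells sorted from mouse tumours were profiled by single-cell RNA sequencing. The tumours were grown from MC38-EGFP, a mouse colon carcinoma line carrying a green fluorescent protein, in wild-type C57BL/6 mice. The sorts were for cDC1, a subset known for cross-presenting antigen to cytotoxic T cells, and cDC2, a subset known for presenting antigen to helper T cells. The title of the series names WEE1, a kinase that holds cells before mitosis, in tumour-associated dendritic cells, and no treated group was among these libraries. The 6 libraries fell into 3 titled DC1 (numbers 3, 4 and 5) and 3 titled DC2 (numbers 1, 2 and 6), each with 96 barcoded wells. The titles were read as the cDC1 and cDC2 sorts, and their numbers, called replicates here, may be those of plates. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. The DC1 libraries held 157942431, 82141412 and 77736270 reads in replicates 3, 4 and 5, and the DC2 libraries 51668923, 61229508 and 133135075 in replicates 1, 2 and 6. Of 576 wells, 567 passed the filter of 1000 detected genes, with a median of 156657 to 1024140 reads per cell in a library. The values were reads and not molecules, so intervals and floors cover counting error only.

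The first question was which cell states each sort contained. Mature-like cells, a cluster led by Ccr7, the receptor for migration to lymph nodes, and Fscn1, an actin-bundling protein of mature dendritic cells, made up 20.8% ± 4.77 of DC1 cells (SD, n = 3) and 2.14% ± 1.05 of DC2 cells (SD, n = 3), a difference of 18.7 percentage points. The lowest DC1 library, replicate 4, had 16.7% (95% Clopper-Pearson interval 9.84 to 25.7), and the highest DC2 library, replicate 6, had 3.19% (0.663 to 9.04). A cDC1-like cluster, led by Cd24a, Wdfy4, Xcr1 and Clec9a, made up 9.72% ± 2.62 of DC1 cells and 0 of the DC2 cells. For these counts of 0 the 95% Clopper-Pearson interval reached up to 3.89%, 3.93% and 3.85% in DC2 replicates 1, 2 and 6. Macrophage-like cells, in clusters led by C1qa, Apoe and Mrc1 or by Retnla and Ccl6, made up 3.47% ± 1.59 of DC1 and 20.1% ± 6.89 of DC2 cells, and 18.0% ± 7.12 and 53.5% ± 11.6 when only cells with at least 100000 reads were clustered. T or NK-like cells made up 3.82% ± 1.203 and 6.07% ± 3.21. No cluster was cycling-like. None was named cDC2-like in this clustering, while with scaled genes a cluster of 97 cells took that name and held 13.2% ± 1.203 of DC1 and 21.1% ± 1.51 of DC2 cells. That cluster was led by Thbs1, Cxcl2 and Klf4, and of its 4 cDC2 markers only Klf4 was among the 10 leading genes. Klf4 and Cxcl2 were also among the leading genes of the macrophage-like cluster led by Retnla and Ccl6. The name therefore does not show that a cDC2 population was found. The two-sided exact permutation p was 0.1 for the mature-like, cDC1-like and macrophage-like shares, the smallest that 3 against 3 libraries allow, and 0.2 for the T or NK-like share.

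Much of both sorts stayed without a class. Unnamed clusters made up 34.4% ± 6.51 of DC1 and 30.5% ± 2.19 of DC2 cells (SD, n = 3 each). Cluster 3, led by Arg1, an arginine-degrading enzyme of myeloid cells, and Spp1, the secreted protein osteopontin, had 3.13% of DC1 and 12.5% of DC2 cells. Cluster 4, led by Ly6i, Il1rn and Fcgr2b, had 17.7% and 13.6%, and cluster 6, led by Il1r2, Napsa and H2-Ob, had 13.5% and 4.29%. By number of markers the best class was cDC2-like for cluster 3 and monocyte-like for cluster 4. Each had 3 such markers, with 0 among its 10 leading genes, and so took no name. For cluster 6 the best class was mature-like, with 2 markers, under the 3 needed. Clusters with a median depth under 1/3 of the library median, a bound set after the clusters were seen, were kept apart as shallow and made up 27.8% ± 4.92 of DC1 and 41.3% ± 8.55 of DC2 cells. Among them, cluster 8 carried mature-like markers and held 22.9% ± 6.25 of DC1 and 0.362% of DC2 cells, while clusters 2 and 9 carried macrophage-like markers and held 4.86% and 0 of DC1 and 25.7% ± 17.6 and 15.2% ± 25.4 of DC2 cells. Cluster 9 was nearly all from DC2 replicate 2, with 41 of its 42 cells. At a clustering resolution of 0.5 the cDC1-like class was wider and held 57 DC1 and 11 DC2 cells, and the macrophage-like share of DC2 was 37.9%. Naming the shallow clusters by their best class moved the mature-like difference to 41.2 points. Doublets were not called.

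**Figure D1:**
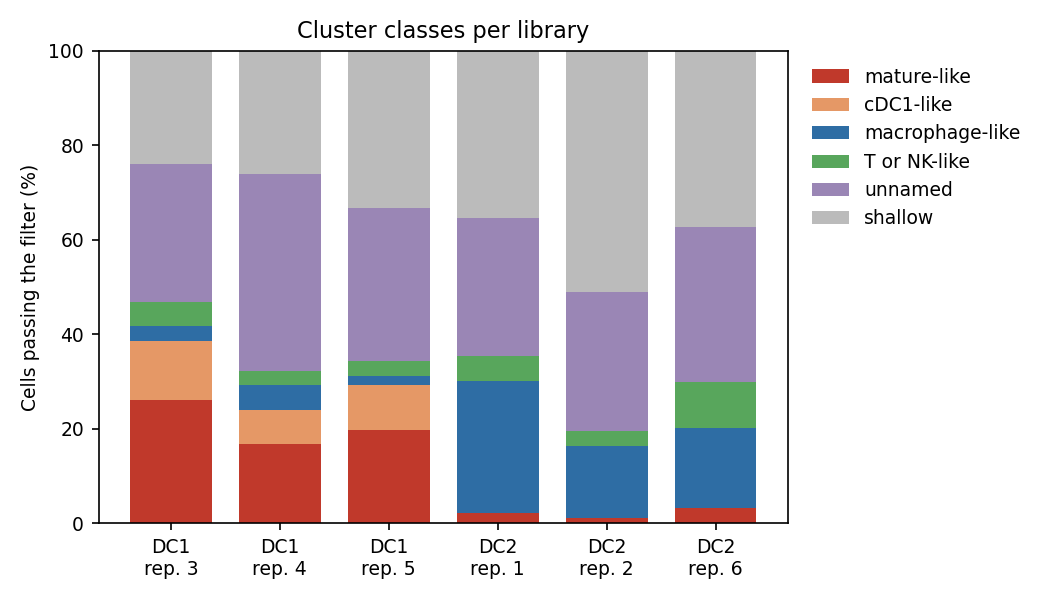
Stacked bars give the share of cells passing the filter (%) in each cluster class, 1 bar per library. The mature-like share lies between 16.7% and 26.0% in the 3 DC1 libraries and between 1.09% and 3.19% in the 3 DC2 libraries.

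Summed over all cells of a library, the genes that were higher in DC1 were led, among those with a mean log2 CPM of at least 5, by Plet1, Slc27a3 and Mreg. Plet1, a surface protein found on subsets of dendritic cells (mm10 chromosome 9, 50494525 to 50505482), stood at 293 ± 125 CPM (reads scaled to a common library total after TMM normalisation) in DC1 and 13.7 ± 6.82 in DC2 (SD, n = 3 each), a log2 fold change of 4.42 ± 0.45 (SE, adjusted p = 0.00264). Slc27a3, a fatty acid transport protein, followed at 3.62 ± 0.75 (adjusted p = 0.0467), and Mreg, a protein of organelle transport, at 3.43 ± 0.44 (adjusted p = 0.00795). The other 9 of the 12 largest by the naming rule were Laptm4b (3.33), Ncoa7 (3.21), Slc25a38 (3.21), Cd24a (3.12), Ears2 (3.02), Scin (2.89), Flt3 (2.84), Bcl2l14 (2.80) and Tbc1d8 (2.77). Among DC1 reads, 84.2% of those of Plet1 lay in the cDC1-like cluster, and 94.2% of those of Slc27a3 and 86.8% of those of Mreg in the mature-like cluster. In DC1 replicates 3, 4 and 5, 6, 5 and 7 wells held 90% of the Plet1 reads. A single well of replicate 3 held 68.2% of the 60494 there. The mature-like cells held 22.3% of all DC1 reads and 2.49% of all DC2 reads.

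The genes that were higher in DC2 were led, with the same limit, by Folr2, a folate receptor of tissue macrophages (chromosome 7, 101839988 to 101857194), which had 20808 reads in DC2 and 20 in DC1, a log2 fold change of -10.11 ± 0.79 (SE, n = 3 against 3, adjusted p = 0.000513). Pf4, a platelet and macrophage chemokine, changed by -3.12 ± 0.50 and Ms4a7, a membrane protein of macrophages, by -3.01 ± 0.57. Arg1 stood at 911 ± 700 CPM in DC1 and 5765 ± 403 in DC2 (SD, n = 3 each), and Apoe, the lipid carrier apolipoprotein E, at 1385 ± 851 and 7772 ± 1977. The other 7 of the 12 largest were Tmem37 (-2.53), Sepp1 (-2.43), Rnase4 (-2.36), Ccl6 (-2.15), Mgst1 (-2.00), Ctsd (-1.96) and Ifit3 (-1.86). Of the DC2 reads of Folr2, pooled over the libraries, 52.6% lay in macrophage-like and 43.4% in T or NK-like clusters, and 3 to 7 wells of a DC2 library held 90% of them. Arg1 had 61.9% of its DC2 reads in unnamed clusters.

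Over 11472 tested genes, 131 were higher in DC1 and 51 were higher in DC2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 1371 had an unadjusted p under 0.05. In data simulated with the spread estimated from these libraries the same test called 0% of 2-fold, 32% of 4-fold, 56.2% of 8-fold and 68% of 16-fold changes, while in the real libraries some genes with changes under 2-fold were called, such as Psme1 (0.89). The counts in the DC1 and DC2 directions were 32 and 13 without DC1 replicate 3, 129 and 113 without DC1 replicate 4, 40 and 16 without DC1 replicate 5, 68 and 33 without DC2 replicate 1, 49 and 11 without DC2 replicate 2, and 59 and 13 without DC2 replicate 6. Of 47 called genes named here, 13 kept the call in each of these 6 fits (Plet1, Mreg, Slc25a38, Folr2, Sepp1, Irf8, Ccr7, Itgae, Cd209d, Samsn1, Ccl22, H2-Ob and Timd4), and 21, 43 and 24 did so without DC1 replicates 3, 4 and 5 and 31, 19 and 24 without DC2 replicates 1, 2 and 6. Without mature-like cells 25 genes were higher in DC1 and 14 in DC2, and without mature-like and cDC1-like cells 4 (Cd209d, Cst3, Ifitm1 and Syngr2, the last 3 outside the naming rule) and 2 (Folr2 and Igf1, the latter outside it).

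**Figure D2:**
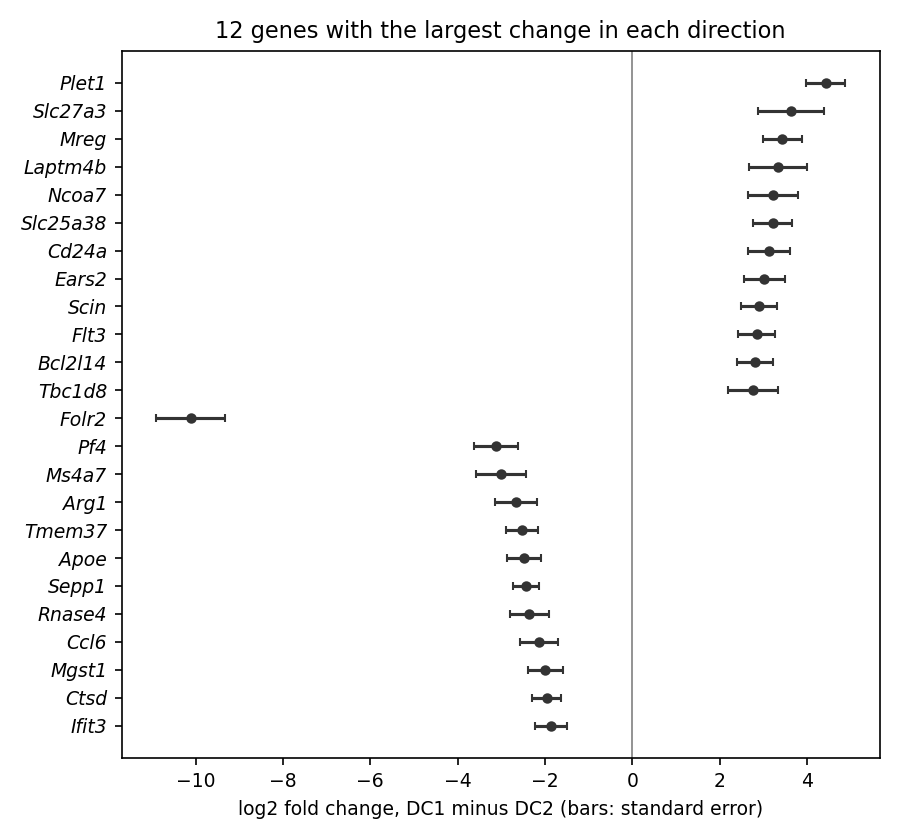
Points give the log2 fold change, DC1 minus DC2, and bars its standard error for the 12 genes with the largest change in each direction by the naming rule. Plet1 has the largest value in the DC1 direction, 4.42, and Folr2 the largest in the DC2 direction, -10.11.

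The sort was next compared with the known markers of the subsets. Itgae, the integrin CD103 of cDC1, stood at 52.96 ± 4.15 CPM in DC1 and 1.21 ± 0.573 in DC2 (SD, n = 3 each; log2 fold change 5.44 ± 0.46, adjusted p = 0.000787), and Irf8, the transcription factor of the cDC1 lineage, at 1459.6 ± 323 and 480 ± 77.4 (1.61 ± 0.21, adjusted p = 0.00884). Cd24a, a surface glycoprotein of cDC1, was also higher in DC1 (3.12 ± 0.48, adjusted p = 0.0148). The chemokine receptor Xcr1 and the dead-cell receptor Clec9a, which mark cDC1, had values of 2.64 ± 0.60 (adjusted p = 0.0637) and 2.41 ± 0.60 (adjusted p = 0.0908), each with all 3 DC1 libraries above all 3 DC2 libraries, and did not pass the test. Snx22, an endosomal sorting nexin, was called with 2408 reads in DC1 and 1 read in DC2. In each DC1 library 2 wells held 90% of the Snx22 reads, and its call was kept only without DC1 replicate 4. For Itgae, 4, 3 and 8 wells held 90% of the reads in DC1 replicates 3, 4 and 5. Of 19 tested members of the cDC1 identity list, 5 were called higher in DC1 and 0 lower over all genes, and 15 and 0 adjusted over the list alone. The list median was 1.91 (camera adjusted p = 1.34e-14; adjusted p = 0.140 with an estimated correlation). Of the DC1 reads of Irf8, 52.2% lay in mature-like and 19.9% in cDC1-like cells, and its mean was 2956 CPM per mature-like and 1671 per cDC1-like cell. Over the mature-like and cDC1-like cells alone the value of Irf8 was -0.85. The 6 DC2 cells there were all mature-like and the DC1 cells 60 mature-like and 28 cDC1-like. This value and those over the same cells below therefore compare different mixes of clusters.

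Markers of cDC2 did not move one way. Sirpa, an inhibitory receptor of cDC2, had a log2 fold change of -1.03 ± 0.28 (adjusted p = 0.124), Itgam, the integrin CD11b, -1.27 ± 0.34 (adjusted p = 0.111), Irf4, a transcription factor of cDC2 and of maturation, 0.97 ± 0.66 (adjusted p = 0.674) and Cd209a, a lectin of cDC2, 0.83 ± 0.59 (adjusted p = 0.692), and none of these 4 passed the test. Of 20 tested members of the cDC2 identity list, edgeR called 2 higher in DC1 and 0 in DC2 over all genes, and 3 and 6 adjusted over the list alone. DESeq2 called 3 higher in DC1 and 4 in DC2, and limma-voom 2 and 4. Both members called by edgeR over all genes were higher in DC1. Relb, a transcription factor of dendritic cell maturation that is also in the maturation list, had 1.28 ± 0.19 (adjusted p = 0.0138). Cd209d, a lectin related to Cd209a, had 5518 reads in DC1 and 0 in DC2, at least 1424-fold higher against a floor of 3 reads over the group (adjusted p = 0.00471), and 1 or 2 wells held 90% of them in each DC1 library. The list median was -0.63 and its mean 0.28, or 0.13 with Cd209d at its bound, and the test pointed to DC2 (camera adjusted p = 0.0277; adjusted p = 0.257 with an estimated correlation), with no call without DC1 replicate 5 (adjusted p = 0.0827). Macrophages also express Sirpa and Itgam, and macrophage-like cells were 20.1% of DC2 and 3.47% of DC1 cells, or 53.5% and 18.0% among cells with at least 100000 reads.

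The 2 called genes of all conventional dendritic cells were higher in DC1. Flt3, the receptor for the growth factor of dendritic cells, stood at 61.5 ± 24.4 CPM in DC1 and 8.55 ± 3.15 in DC2 (SD, n = 3 each; log2 fold change 2.84 ± 0.43, adjusted p = 0.0138), and Zbtb46, a transcription factor of the conventional lineage, at 26.4 ± 8.22 and 5.28 ± 1.35 (2.32 ± 0.47, adjusted p = 0.0428). Of 10 tested members of the pan-dendritic list, 2 were called higher in DC1 and 0 in DC2, and 5 and 0 adjusted over the list alone. The list median was 1.93 (camera adjusted p = 9.75e-06; adjusted p = 0.115 with an estimated correlation). Zbtb46 kept its call only without DC1 replicate 4, and Flt3 lost it without DC1 replicate 3. Over the mature-like and cDC1-like cells alone, where the DC2 libraries had 2, 1 and 3 cells, all mature-like, and the DC1 libraries cells of both classes, the values were -1.87 for Flt3 and -1.51 for Zbtb46. The mean of Flt3 was 207 CPM per mature-like and 99.1 per cDC1-like cell, and that of Zbtb46 80.7 and 14.5.

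**Figure D3:**
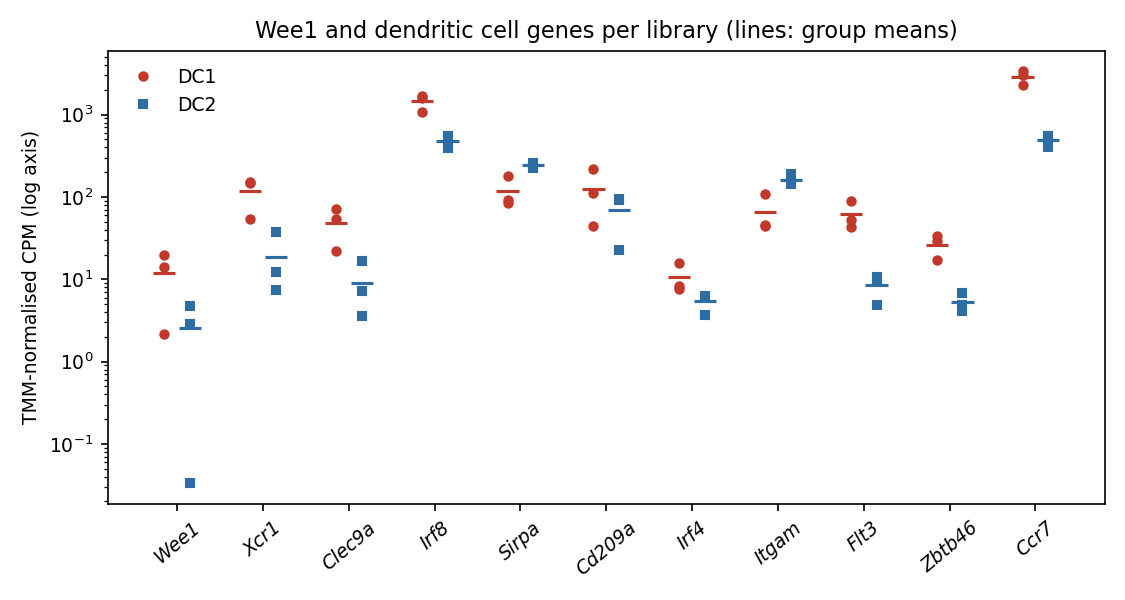
Points give TMM-normalised CPM on a log axis for each library, circles for DC1 and squares for DC2, and lines the group means, for Wee1 and 10 dendritic cell genes. Ccr7 and Irf8 stand apart between the groups, with means of 2885 and 486 CPM for Ccr7, and the Wee1 values of the groups overlap, with 0.0334 CPM in DC2 replicate 2.

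The called genes of dendritic cell maturation were higher in DC1. Ccr7 stood at 2885 ± 545 CPM in DC1 and 486 ± 71.6 in DC2 (SD, n = 3 each), a log2 fold change of 2.57 ± 0.20 (adjusted p = 0.000513). Fscn1 had 2.37 ± 0.36 (adjusted p = 0.0148) and Samsn1, an adaptor protein of immune cells, 1.62 ± 0.20 (adjusted p = 0.00617). Of 19 tested members of the maturation list, 7 were called higher in DC1 and 0 lower, and 15 and 0 adjusted over the list alone, with a median of 1.28 (camera adjusted p = 1.14e-19; adjusted p = 0.115 with an estimated correlation). In the list of regulatory genes of mature cells, Ccl22, a chemokine that attracts regulatory T cells, had 2.63 ± 0.31 (adjusted p = 0.00518) and Cd200, an inhibitory ligand, 2.58 ± 0.44 (adjusted p = 0.0215). These were the 2 of 12 tested members called higher in DC1, with 0 lower, and 4 and 0 adjusted over the list alone, with a median of 0.84 (camera adjusted p = 0.000379; adjusted p = 0.257 with an estimated correlation). Ccr7, Fscn1, Samsn1, Ccl22, Cd200 and Relb are also among the markers that named the mature-like class, which was 20.8% of DC1 and 2.14% of DC2 cells, so these values are not independent of the shares. The mature-like cells held 71.8% of the DC1 reads of Ccr7 and 93.8% of those of Fscn1. Of the DC2 reads of these genes, pooled over the libraries, 34.3% and 34.9% lay in T or NK-like clusters. Over the cells without the mature-like and cDC1-like classes Ccr7 had 2.50 ± 0.66 (SE, edgeR adjusted p = 0.390). Its call ended with a wider error at a similar value, while Fscn1 had 0.92 ± 0.87 (adjusted p = 0.976). These cells still held clusters 6 and 8, whose best class by markers was mature-like. Cluster 6 had 39 DC1 and 12 DC2 cells with a mean Ccr7 of 2367 CPM, and cluster 8 had 66 and 1 with 2820 CPM. A Ccr7 difference outside mature cells therefore cannot be read from this value. Over the mature-like and cDC1-like classes alone, with DC2 cells of the mature-like class only, Ccr7 had -1.203. Its mean was 9601 CPM per mature-like and 520 per cDC1-like cell, and its median 8652 and 52.4.

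The antigen presentation genes called by edgeR came in 2 pairs. Psme1 and Psme2, subunits of the proteasome activator that aids the making of MHC class I peptides, were higher in DC1 with log2 fold changes of 0.89 ± 0.16 (adjusted p = 0.0255) and 0.77 ± 0.16 (adjusted p = 0.0460; n = 3 against 3), and lie on chromosome 14, at 55578123 to 55581529 and 55587441 to 55591113. These were the 2 of 17 tested MHC class I members called higher in DC1, with 0 lower, and 4 and 0 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.00278; adjusted p = 0.140 with an estimated correlation). H2-Ob and H2-Oa, the chains of the H2-O protein that restrains peptide loading on MHC class II, had 2.49 ± 0.32 (adjusted p = 0.00783) and 2.30 ± 0.38 (adjusted p = 0.0189). They were the 2 of 14 tested MHC class II members that edgeR called higher in DC1, with 0 lower, and 6 and 2 adjusted over the list alone. DESeq2 and limma-voom each called 5 higher in DC1 and 1 in DC2. The list median was 0.44 (camera adjusted p = 0.000301, and adjusted p = 0.257 with an estimated correlation). Of the DC1 reads of H2-Ob, 49.3% lay in the cDC1-like cluster and 39.9% in unnamed clusters. Psme2 lost its call without each of the 6 libraries in turn, and Psme1 kept it only without DC1 replicate 4. Over the mature-like and cDC1-like cells alone, with 6 DC2 cells, all mature-like, Psme1 had -0.67 and Psme2 -0.61.

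Genes of antigen uptake and cross-presentation went both ways. Timd4, a receptor for phosphatidylserine on dying cells (chromosome 11, 46810800 to 46844332), had 10452 reads in DC1 and 0 in DC2, at least 2697-fold higher against a floor of 3 reads over the group (adjusted p = 0.00264), with 5 to 7 wells of a DC1 library holding 90% of them. Cybb, the catalytic subunit of the phagocyte oxidase, and Fcgr3, an activating receptor for antibodies, were higher in DC2 with log2 fold changes of -1.05 ± 0.20 (adjusted p = 0.0342) and -1.10 ± 0.23 (adjusted p = 0.0467; n = 3 against 3). Of 20 tested members 1 was called higher in DC1 and 2 in DC2, and 4 and 7 adjusted over the list alone. The list median was -0.36 and its mean 0.63, or 0.46 with Timd4 at its bound, and the test pointed to DC2 (camera adjusted p = 0.0433; adjusted p = 0.257 with an estimated correlation). The call was lost without DC1 replicate 3 (adjusted p = 0.145), DC1 replicate 5 (0.0827), DC2 replicate 2 (0.0511) or DC2 replicate 6 (0.132), and Cybb and Fcgr3 each kept theirs only without DC1 replicate 4. Macrophage-like clusters held 36.6% of the DC2 reads of Cybb and 29.3% of those of Fcgr3.

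The called genes of macrophages and lysosomes were higher in DC2. Apoe, Ms4a7, Arg1 and Cd68, a lysosomal glycoprotein of macrophages (log2 fold change -1.05 ± 0.19, adjusted p = 0.0278), were the 4 of 15 tested macrophage markers called higher in DC2, with 0 higher in DC1, and 13 and 0 were so adjusted over the list alone, with a median of -1.43 (camera adjusted p = 8.40e-21; adjusted p = 0.138 with an estimated correlation). Ctsd and Ctsl, lysosomal proteases, had -1.96 ± 0.33 (adjusted p = 0.0198) and -1.65 ± 0.28 (adjusted p = 0.0209), and Lyz2, a lysozyme with a close copy that may share its reads, stood at 9891 ± 2432 CPM in DC1 and 23686 ± 2501 in DC2 (SD, n = 3 each; -1.26 ± 0.19, adjusted p = 0.0129). The lysosome and complement list, which also holds Apoe and Cd68, had 6 of 19 tested members higher in DC2 and 0 in DC1, and 16 and 0 adjusted over the list alone, with a median of -1.05 (camera adjusted p = 1.29e-22; adjusted p = 0.140 with an estimated correlation). Cd68 kept its call only without DC1 replicate 4, and over the mature-like and cDC1-like cells alone, with 6 DC2 cells, all mature-like, its value was 2.45. Without the macrophage-like cells 87 genes were higher in DC1 and 51 in DC2, of which 73 and 32 were called with them.

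Markers of other cells that a sort can carry over were measured in the same way. Of 11 tested monocyte markers 0 were called over all genes, by edgeR, with 3 at an unadjusted p under 0.05, while DESeq2 called 3 and limma-voom 2 higher in DC2, and 2 were higher in DC2 adjusted over the list alone. The monocyte median was -0.99 (camera adjusted p = 0.000956; adjusted p = 0.140 with an estimated correlation). Of 11 tested T and NK markers 0 were called by edgeR, with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, and 0 adjusted over the list alone. Their median was -0.57 (camera adjusted p = 0.0277; adjusted p = 0.472 with an estimated correlation), with no call without DC1 replicate 4 (0.0733), DC1 replicate 5 (0.116) or DC2 replicate 6 (0.352). Pooled over the libraries of a group, the T or NK-like cells held 7.10% of DC1 and 17.0% of DC2 reads. Most of these DC2 reads came from replicate 6, which had 9 such cells against 5 and 3 in replicates 1 and 2. The pooled DC2 share therefore does not describe each DC2 library. No list was called for neutrophils (3 tested members, camera adjusted p = 0.0953), B and plasma cells (1, 0.381), plasmacytoid dendritic cells (5, 0.901), MC38 carcinoma and epithelium (5, 0.235), fibroblasts and endothelium (8, 0.300) or mast cells and basophils (1, 0.112). In these 6 lists edgeR called 0 members over all genes, with 3 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. Kit was among these 3 and was higher in DC1. Kit was the single tested mast cell and basophil gene, so no adjustment over that list applied, and is also in the pan-dendritic list.

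**Figure D4:**
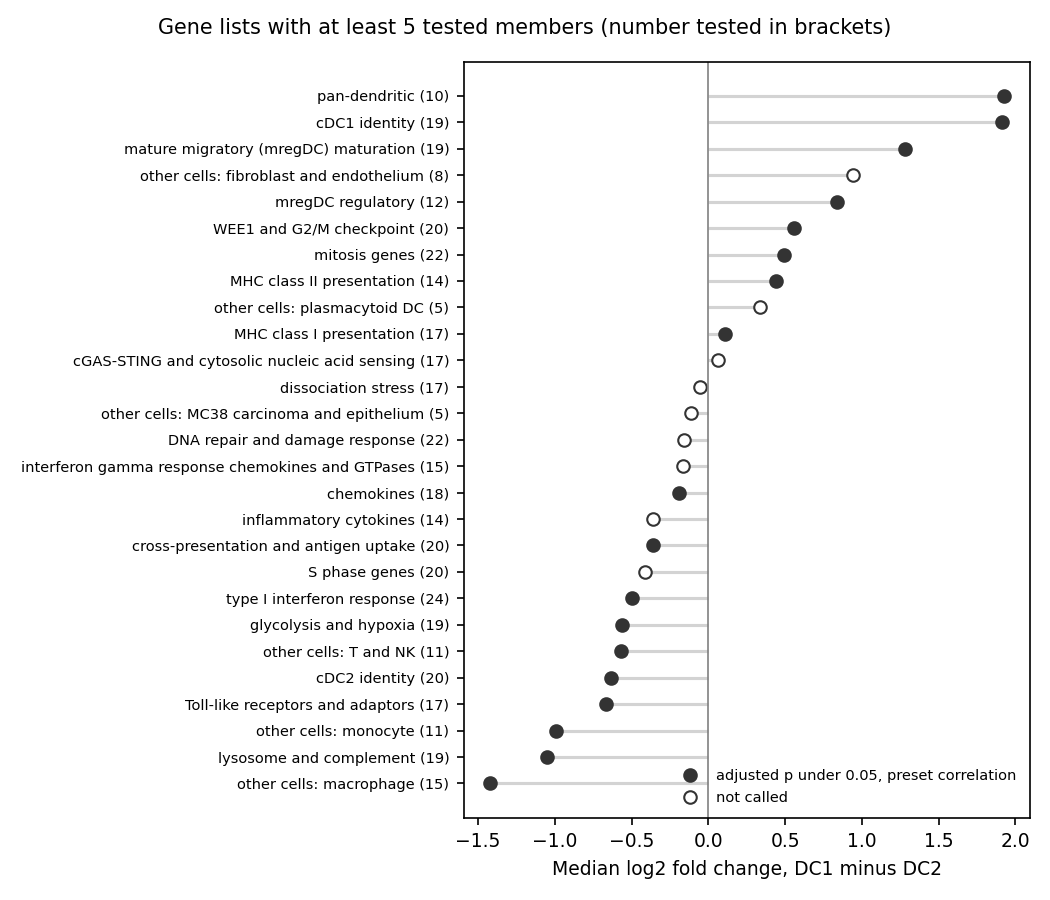
Points give the median log2 fold change, DC1 minus DC2, of each gene list with at least 5 tested members, filled where the camera adjusted p with a preset correlation was under 0.05. The pan-dendritic list is highest at 1.93 and the macrophage list lowest at -1.43.

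Wee1, the gene in the series title (chromosome 7, 110122046 to 110143286, plus strand), was read at a low level. It stood at 12.01 ± 8.94 CPM in DC1 and 2.54 ± 2.37 in DC2 (SD, n = 3 each), a log2 fold change of 2.24 ± 1.32 that did not pass the test (adjusted p = 0.595). The libraries overlapped, with 2.19, 19.7 and 14.2 CPM in DC1 replicates 3, 4 and 5 and 4.75, 0.0334 and 2.83 in DC2 replicates 1, 2 and 6. DC2 replicate 2 had 2 reads, and 2 to 5 wells of a library held 90% of its Wee1 reads. Wells with a Wee1 read were 8, 24 and 20 of 96 in the DC1 libraries and 19, 2 and 15 of 93, 92 and 94 in the DC2 libraries. Without the macrophage-like cells the value was 1.82 (adjusted p = 0.773), and without them among cells with at least 100000 reads 4.92 (adjusted p = 0.259). With a library left out it ranged from 1.67, without DC2 replicate 2, to 3.06, without DC2 replicate 1.

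Other cell cycle genes were not called singly. Of 20 tested members of the WEE1 and G2/M checkpoint list 0 were called over all genes by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and 0 adjusted over the list alone. The list median was 0.56 (camera adjusted p = 0.0277; adjusted p = 0.472 with an estimated correlation). Of 22 tested mitosis genes 0 were called, with 1 at an unadjusted p under 0.05 and 1 each by DESeq2 and limma-voom, and 1, Top2a, was higher in DC1 adjusted over the list alone. The mitosis median was 0.49 (camera adjusted p = 0.0108; adjusted p = 0.472 with an estimated correlation). Both list calls were lost without DC1 replicate 4 (0.0545 for the checkpoint and 0.0571 for the mitosis list), DC1 replicate 5 (0.0885 and 0.112) or DC2 replicate 6 (0.686 and 0.771), and without the last the direction of both tests turned. Of 20 tested S phase genes 0 were called, with 2 at an unadjusted p under 0.05 and 0 by both other tools, and 0 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.880). Of 22 tested DNA repair genes 0 were called, with 4 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma-voom, and 1 was higher in DC1 adjusted over the list alone. The repair median was -0.16, its mean 0.07 and the test pointed to DC1 (camera adjusted p = 0.689).

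Wee1 was also compared between mature-like and other cells of the 3 DC1 libraries. The other cells were all those not named mature-like, among them cDC1-like, T or NK-like, macrophage-like, unnamed and shallow cells. Over both groups the mean of Top2a was 105 CPM per cDC1-like, 61.9 per T or NK-like and 2.87 per mature-like cell. The comparison therefore does not separate maturation from cell class. Its mean was 12.1 ± 17.2 CPM in mature-like and 9.44 ± 9.02 CPM in other cells (SD, n = 3 libraries), a log2 fold change of 0.18 ± 2.04 with the library as a block (edgeR adjusted p = 0.974 over all genes and 0.932 adjusted over the list alone). The reads were 121, 5 and 647 in mature-like cells and 206, 1561 and 518 in other cells of replicates 3, 4 and 5. The value was -1.34 without replicate 3, 1.68 without replicate 4 and -1.77 without replicate 5. The cyclins and phosphatase of mitotic entry had values of -5.23 ± 1.56 for Ccnb2 (adjusted p = 0.0618), -6.53 ± 2.21 for Ccnb1 (adjusted p = 0.105), -8.67 ± 2.96 for Cdc25b (adjusted p = 0.106) and -6.44 ± 2.24 for Ccna2 (adjusted p = 0.113), each at 0.0572 adjusted over the list alone. Mature-like cells of replicates 3, 4 and 5 held 9, 9 and 7 reads of Ccnb2 and 1, 2 and 1 of Ccnb1. They held 1, 0 and 0 reads of Cdc25b and 9, 0 and 3 of Ccna2. With so few reads on that side, the sizes of these 4 values are not reliable. Of 19 tested members of the checkpoint list 0 were called in either way, with 15 below 0 and 8 at an unadjusted p under 0.05, and no other tool was run on this comparison. The genes of this list were left out of the clustering.

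The other comparisons of the design could not be fitted. The DC2 libraries held 2, 1 and 3 mature-like and 0 cDC1-like cells, fewer than the 5 per library that a fit within these classes or of their difference required. No cluster was cycling-like, so its share and the level of Wee1 in it were not measured. No measured feature was named EGFP or GFP, so the label of the tumour cells was not followed.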

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

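All tests on subsets of cells, with mature-like and cDC1-like, macrophage-like or shallow cells left out or clusters 0, 3, 4 and 5 alone, and the test of total reads on the gene counts were chosen after the data were seen, and those of reads under a wrong barcode and of other splits before their results. In each library a column outside the numbered barcodes held reads that no comparison used. It held 3.03%, 3.30% and 3.01% of all reads in DC1 replicates 3, 4 and 5 and 3.51%, 3.29% and 3.52% in DC2 replicates 1, 2 and 6, and was flagged only because more than 3 reads lay there, which says nothing about their source. Its profile followed that of its own library, with Spearman correlations across genes, which are not independent replicates, of 0.92 to 0.944.

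The first pattern weighed was this column together with the shallow wells, whose profiles resembled their library. Genes with at least 1000 reads in 1 well and 90% of a library's reads there had a read in shallow wells of the same library 2.41 times as often as in those of the other libraries (median of 6 libraries, 1.36 to 5.18), and 2.79 times at bounds of 95% and 2000 reads (median of 5 libraries with 2 to 7 such genes, as DC2 replicate 1 had 0). This is consistent with reads of 1 well being counted under the barcodes of others in the same pool, which may be part of what shallow wells hold. For the column the ratio was 1.49 (1.27 to 2.14), but 100% of such genes had a read in their own column in each library, so the measure was saturated and the explanation cannot be told apart from others there. No biological explanation was tested for either.

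The second pattern was the set of genes higher in DC1. A greater total of reads as the cause was argued against by thinning each library to 51662827 reads, at which 130 of the 131 genes kept the call, with reads per cell not matched. More mature-like and cDC1-like cells in the DC1 libraries may account for part of the set. Without the cells so named the median log2 fold change of the called genes was 1.12, against 1.79 over all cells. This lies between the bounds that would argue for or against makeup as the main cause. Clusters 6 and 8, whose best class by markers was mature-like, were kept there. Over clusters 0, 3, 4 and 5 alone the median was 0.77, past the bound that argues for makeup, with 0 of the 131 calls kept, though in fewer cells and without cluster 6, the T or NK-like and the shallow cells as well. The share due to the makeup of the sorts therefore cannot be told apart from differences within cells, and a difference between the subsets stays open as untested. Of 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 182 genes and the highest other 0, and for lists 1 gave as many as 18 and the highest other 13, and 10 splits are too few for a share under 0.05.

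The third pattern was the set of genes higher in DC2, led by macrophage genes. More cells of the clusters named macrophage-like in DC2 were argued against as the whole cause. Without these clusters the median log2 fold change was -1.59, as over all cells, though unnamed and shallow clusters with macrophage genes were kept. Among cells with at least 100000 reads, where the name covered 53.5% of DC2 and 18.0% of DC1 cells, it was -1.79 without them against -1.59 with them. There 26 of the 51 genes kept the call. An unnamed cluster led by Arg1, whose best class by markers was macrophage-like, was kept there. It had 8, 16 and 8 cells in DC2 replicates 1, 2 and 6 and 6, 2 and 0 in DC1 replicates 3, 4 and 5. The T or NK-like cells were kept as well. Neither value can therefore speak against macrophage genes from the cells that were kept. Over clusters 0, 3, 4 and 5 alone, which hold all cells named macrophage-like of both groups, the median was -0.67, past the same bound, with 1 of the 51 calls kept. This goes with the makeup of the sorts in the other clusters, though again in fewer cells and without cluster 6, the T or NK-like and the shallow cells. Without the shallow wells the median was -1.60, so their own reads were not the main source of the difference in sums. Shallow clusters 2, 8 and 9 held only 7.48%, 0.72% and 0.91% of DC2 reads and 1.29%, 2.81% and 0% of DC1 reads. Leaving them out could therefore move the sums little, and this value decides nothing more about shallow wells. Without the mature-like and cDC1-like cells the median was -1.02, between the bounds, so that a lower share of other cells in DC1 may account for part of it and cannot be told apart from differences within cells. A difference between the sorted subsets, including cells of the macrophage lineage in the cDC2 gate, stays open as untested.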

How the results depend on the processing

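The alternatives without shallow, T or NK-like, macrophage-like or mature-like and cDC1-like cells, with clusters 0, 3, 4 and 5 alone, with at least 100000 reads per cell, with these but no macrophage-like cells, with scaled genes and with shallow clusters named were chosen after the data were seen. Among 1266 values of the named genes 906 kept direction and side of the threshold, 313 lost the call, 23 gained it and 24 turned, and among 718 values of the lists 603, 85, 13 and 17. Genes higher in DC1 and in DC2, 131 and 51, numbered 365 and 295 with DESeq2, 178 and 154 with limma-voom, 256 and 180 without a gene filter, 273 and 299 with equal weight per cell, 25 and 14 without mature-like cells, 4 and 2 without mature-like and cDC1-like cells (edgeR, 711 at an unadjusted p under 0.05), 87 and 51 without macrophage-like cells, 67 and 67 without them among cells with 100000 reads, 0 and 1 (Folr2; 572 unadjusted) in clusters 0, 3, 4 and 5, and 4 (Cd24a, Ckb, H2-Ab1 and Plet1) and 0 (1826 unadjusted) in DC-like cells alone. With a library left out they ranged from 32 to 129 and from 11 to 113. Lists called, 18, numbered 0 with an estimated correlation, 4 with fry, 11 in DC-like cells, 20 without macrophage-like cells among those with 100000 reads, 10 without mature-like and cDC1-like cells, and 12 to 18 with a library left out. In DC-like cells alone, those of the mature-like and cDC1-like clusters, the DC2 libraries had 2, 1 and 3 cells, all mature-like, against 60 mature-like and 28 cDC1-like DC1 cells, so the groups hold different clusters, and the median of all genes was 0.38. There the log2 fold change was -0.99 for Slc27a3, -0.39 for Mreg, -1.42 for Scin, -1.87 for Flt3, -0.072 for Tbc1d8, -0.85 for Irf8, -0.38 for Irf4, -1.51 for Zbtb46, -1.20 for Ccr7, -1.40 for Relb, -1.28 for Samsn1, -1.37 for Fscn1, -0.84 for Ccl22, -0.59 for Cd200, -0.67 for Psme1, -0.61 for Psme2, 0.12 for Fcgr3, 0.67 for Ccl2, 1.09 for Lyz2, 0.94 for Ctsl and 2.45 for Cd68. The tests of these lists turned there, with medians of 0.42 for pan-dendritic, -1.20 for maturation, -0.037 for regulatory, -0.61 for MHC class I, 0.98 for cross-presentation, 1.41 for type I interferon, 0.54 for Toll-like receptors and 2.68 for monocyte genes. In clusters 0, 3, 4 and 5 Xcr1 had -0.038 and Zbtb46 -0.13, and list tests turned with medians of 0.19 for cross-presentation, 0.23 for type I interferon, 0.035 for Toll-like receptors, -0.78 for the checkpoint, -1.14 for mitosis and 0.12 for glycolysis. The cross-presentation test also turned without mature-like and cDC1-like cells, at 0.14, and the checkpoint and mitosis tests without DC2 replicate 6, at 0.20 and 0.15, with a range over the libraries left out of 0.20 to 0.77 and of 0.066 to 1.03. With equal weight per cell Irf4 had -0.0092. Wee1 in mature-like against other cells, 0.18, ranged from -1.77 without DC1 replicate 5 and -1.34 without replicate 3 to 1.68 without replicate 4, and was 0.13 at resolutions 0.5 and 2. Wee1 in DC1 against DC2 was not called in any alternative, with adjusted p of 0.237 to 0.999. Its log2 fold change was 1.67 to 4.92 in the alternatives other than equal weight per cell. With equal weight its value was 0.06 on the scale per cell given for Irf4, which cannot be set against these fold changes. The difference in mature-like share was 20.1 points at both resolutions, 22.4 with 2000 genes per cell, 27.7 with scaled genes, 20.5 with 100000 reads and 16.1 to 20.8 with a library left out. Fewer cells, other mixes of clusters and fewer libraries enter these subsets, and otherwise the cause was not tested. No paired analysis was possible because the groups share no replicate number. Leaving out cells of very high depth removed 0 cells, no cycling-like cells were found to leave out, and Wee1 in DC1 alone is the value given, with no fit in DC2. The low count of Wee1 in DC2 replicate 2, 2 reads, limits its value, and thinning each library to the same total of reads left it at 2.28.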

Other observations

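The count of genes absent from 3 libraries was chosen after the data were seen. Chemokine genes went both ways. Ccl22 was higher in DC1, and Ccl6 and Ccl9, neighbouring myeloid chemokine genes on chromosome 11, were higher in DC2 with log2 fold changes of -2.15 ± 0.44 (SE, edgeR adjusted p = 0.0426) and -1.83 ± 0.29 (adjusted p = 0.0179), as was Ccl2, a chemokine that attracts monocytes, at -1.22 ± 0.26 (adjusted p = 0.0467; n = 3 against 3 libraries). Of 18 tested chemokines 1 was higher in DC1 and 3 in DC2, and 3 and 4 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0418; adjusted p = 0.257 with an estimated correlation). The list was not called without DC1 replicate 5 (0.126), DC2 replicate 2 (0.0511) or DC2 replicate 6 (0.0601), and Ccl2 lost its call without each library in turn. Macrophage-like clusters held 54.1% of the DC2 reads of Ccl6 and 42.5% of those of Ccl9. Of 14 tested inflammatory cytokines edgeR called 0, with 4 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom, and 1 was higher in each group adjusted over the list alone. Their median was -0.36, their mean 0.20 and the test pointed to DC2 (camera adjusted p = 0.247).

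Among interferon and sensing genes 1 was called. Ifit3, an interferon-induced antiviral gene, was higher in DC2 at -1.86 ± 0.36 (edgeR adjusted p = 0.0342), the single member of 24 tested type I interferon genes called over all genes and adjusted over the list alone, with 0 higher in DC1. The median of the list was -0.50 (camera adjusted p = 0.000135; adjusted p = 0.257 with an estimated correlation), with no call without DC2 replicate 6 (0.0875). Of 17 tested Toll-like receptors and adaptors edgeR called 0, with 5 at an unadjusted p under 0.05 and 2 higher in DC2 by DESeq2 and by limma-voom, and 0 adjusted over the list alone. Their median was -0.66 (camera adjusted p = 0.00844; adjusted p = 0.257 with an estimated correlation), with no call without DC1 replicate 3 (0.0893) or DC2 replicate 6 (0.0551). Among 15 tested interferon gamma chemokines and GTPases edgeR called 0, with 2 at an unadjusted p under 0.05, 0 by the other tools and 0 adjusted over the list alone (median -0.17, camera adjusted p = 0.401). Among 17 tested cGAS-STING genes edgeR called 0, with 4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone. The median was 0.06, the mean -0.07 and the test pointed to DC2 (camera adjusted p = 0.516). Of 19 tested glycolysis and hypoxia genes edgeR called 0 over all genes, with 10 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom, and 4 were higher in DC2 and 0 in DC1 adjusted over the list alone (median -0.57, camera adjusted p = 3.02e-07; adjusted p = 0.257 with an estimated correlation). Of 17 tested genes of dissociation stress edgeR called 0, with 4 at an unadjusted p under 0.05 and 1 by DESeq2 and by limma-voom, and 1 was higher in DC2 adjusted over the list alone (median -0.06, camera adjusted p = 0.714).

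Some genes were read in 1 group alone. With 0 reads in 3 libraries and at least 100 in each of the others, 10 genes were absent from the 3 DC2 libraries, Timd4 and Cd209d among them, and 3 from the 3 DC1 libraries. The other 18 choices of 3 libraries gave 0 to 6 genes each.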
